A study of Arabidopsis thaliana with 12 samples.

How the data were processed

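Per the labels' protocols, roots of 4-day-old Arabidopsis seedlings were harvested, total RNA was extracted, mRNA was selected with oligo(dT) beads and fragmented, and libraries were made with dUTP in the second strand. There were 12 libraries, 3 for each of 4 genotypes, and all of them were used. Samples were grouped by title. The genotype label of the ERF114 libraries also carries the name ERF115OX, and the titles were followed.

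The deposited values are a signal per gene and library, the read count of the gene divided by 1 size factor per library, which the authors made with DESeq2. Per the submitters' processing notes, the tools were Trimmomatic 0.39, HISAT2 2.2.1, SAMtools 1.11, featureCounts of Subread 2.0.1 and DESeq2. The genome build, the annotation, the strand setting, the filters and the DESeq2 version are not given in the sources used here, and no coordinates are given for that reason. Gene names, products and neighbours were taken from a copy of the TAIR10.1 annotation, which may not be the one the authors used, and all 37884 genes of the table matched a locus tag in it.

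Reads were recovered from the deposited values as multiples of 1 unit per library. Of 454608 values, 316348 were above 0, and 1 was not a whole number of reads at a relative tolerance of 1e-06. It belongs to PSK5 in ERF115-SRDX 3, where 146.7692 reads are implied, and it was rounded where reads were needed. Size factors recomputed by median of ratios lay within 2.29% of those implied. Depth ran from 47242114 to 48343410 reads per library, and a floor of 3 reads was 2.90 to 3.18 normalized counts. Floors cover counting error only.

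Genes with a mean of at least 10 normalized counts over the 12 libraries were tested, 23375 in all. Values were log2 of the normalized count plus 1, which understates changes of genes with few reads. All 4 groups were fitted together in limma 3.58.1 under R 4.3.3 with moderated variances that follow a trend with expression, and 5 comparisons were taken from that fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples.

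The 30 lists fixed by gene identifier and the 19 families fixed by a name rule were tested with camera at a preset correlation of 0.01, adjusted over the 49 within a comparison. Camera with an estimated correlation and fry were run beside it. Calls were also adjusted over each list alone. Shared and opposite calls of pairs of lines were set beside the numbers that independent lists give and beside 100 simulations of unchanged groups that share the WT libraries.

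The comparisons, the 49 lists, filters, tests, most other settings and the rule for named genes were set before the data were examined. The list of stomatal and cuticle genes, which is not among the 49, was written after the photosynthetic values had been seen and before its own values were tested. For each comparison with WT the rule takes ERF115 and ERF114, and the 7 largest and 7 smallest log2 changes among called genes with no overlap between the 3 libraries of the line and the 3 of WT and a mean of at least 20 in the higher group. It takes the 3 called members with the smallest p in the direction of a called list, for at most 5 lists. For each direct comparison it takes 5 and 5 genes. For shared and for opposite calls it takes the 5 of each kind whose smaller absolute log2 change is largest. Members of group X of the ERF family and phytosulfokine genes are always named, and photosynthetic genes always given as a list.

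Other settings were pseudocounts of 0.5 and 4, no filter, a mean of at least 50, TMM scaling, quantile normalization, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, an absolute log2 change of at least 1, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. In the order of the 5 comparisons (ERF115OX, ERF114OX and ERF115-SRDX against WT, then ERF115OX against ERF114OX and against ERF115-SRDX), edgeR called 7621, 8720, 11557, 1608 and 12996 genes and DESeq2 called 8055, 8917, 11767, 2380 and 12988. A fit of only the groups compared was set for the totals beforehand and added for single genes later. After the data were seen, 3 more settings were added: the mean log2 value of the photosynthetic list per library as a covariate, ERF114OX 1 and ERF115-SRDX 2 left out together, and ERF115-SRDX 1 and 3 left out together, where the lone library is assumed to vary like the other groups.

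The limma test was tested on simulated data with 50 changed genes at each size. It recovered 74, 74 and 76% of genes changed 1.5-fold in ERF115OX, ERF114OX and ERF115-SRDX against WT, 86, 88 and 86% of those raised 2-fold and 94, 94 and 96% of those raised 4-fold. Between libraries of a group, Pearson's r across genes, which are not independent replicates, ran from 0.973 to 0.993. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.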

Results

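Messenger RNA was sequenced from roots of 4-day-old Arabidopsis thaliana seedlings of 4 genotypes, with 3 libraries of each. Wild type was the accession Col-0 (WT). A line overexpressing ERF115 (ERF115OX) and a line overexpressing ERF114 (ERF114OX) carried more of one of a pair of closely related AP2/ERF transcription factors, and a further line expressed ERF115 joined to the SRDX repression motif (ERF115-SRDX), a short peptide that turns a plant transcription factor into a repressor of its targets. The question set by the series was which genes act downstream of ERF115 and ERF114 in roots. Each library held between 47242114 and 48343410 reads counted on genes, and 23375 of 37884 genes had a mean of at least 10 normalized counts over the 12 libraries and were tested. Values are normalized read counts as mean ± SD over 3 libraries, and changes are log2 differences ± SE. For every gene said below to have risen or fallen, all 3 libraries of the first group lay on that side of the mean of the group it was compared with. The labels do not say whether the 3 libraries of a genotype came from separately grown plants, nor how many independent lines were used, so p-values measure the spread between these libraries, which may be technical.

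ERF115 transcript (AT5G07310) was far above WT in both lines built with ERF115, and ERF114 transcript (AT5G61890) in the line built with ERF114. ERF115 reached 36657 ± 1881 normalized counts in ERF115OX and 85592 ± 2823 in ERF115-SRDX, against 6.23 ± 3.95 in ERF114OX. The 3 WT libraries differed widely, at 4.86, 23.4 and 561 normalized counts. ERF114 reached 46518 ± 1835 in ERF114OX, against 19.6 ± 13.4 in WT, 66.3 ± 56.0 in ERF115OX and 19.8 ± 6.35 in ERF115-SRDX. In limma, ERF115 rose by 9.73 ± 1.14 in ERF115OX (adjusted p = 0.00011) and by 10.95 ± 1.14 in ERF115-SRDX (adjusted p = 5.1e-06), and ERF114 rose by 11.33 ± 1.02 in ERF114OX (adjusted p = 1.7e-05). Counting per gene cannot separate transcripts of the transgene from those of the endogenous gene, so these values say nothing about the endogenous copies in the lines that carry them.

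Neither factor was called in the line of the other. The change of ERF114 in ERF115OX was 0.78 ± 1.02 (limma adjusted p = 0.59), with 2.01, 92.5 and 104 normalized counts in the 3 libraries. Without ERF115OX 1 it was 2.46 and passed the threshold (adjusted p = 0.0013). The change of ERF115 in ERF114OX was -2.72 ± 1.14 (limma adjusted p = 0.081), which passed in edgeR (adjusted p = 0.016) and without WT 1 (adjusted p = 0.0072). The genotype label of the ERF114 libraries also carries the name ERF115OX, and the transcript values go with their titles.

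**Figure D1:**
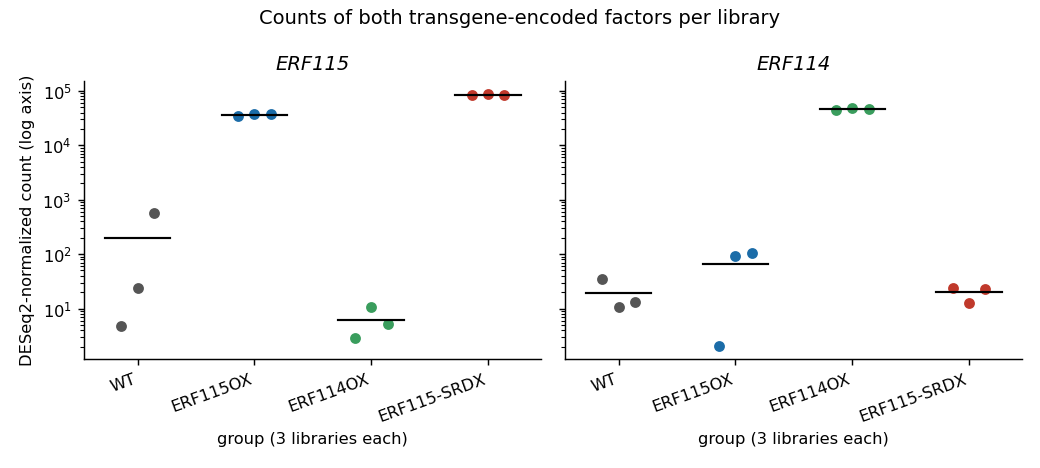
Normalized counts of ERF115 (left) and ERF114 (right) in each library on a log10 axis, with a bar at the group mean. ERF115 lies at 34638 or more in the 6 libraries of ERF115OX and ERF115-SRDX and at 561 or less elsewhere, and ERF114 lies at 44417 or more in ERF114OX and at 104 or less elsewhere.

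The root libraries held transcripts of photosynthetic genes, at levels that differed between genotypes and between libraries of one genotype. The 19 genes of the photosynthetic list (light-harvesting proteins, photosystem subunits, Rubisco subunits and its activase) took 1.68 ± 0.590% of all normalized counts in WT, 0.754 ± 0.139% in ERF115OX, 0.696 ± 0.362% in ERF114OX and 0.114 ± 0.160% in ERF115-SRDX. Their mean log2 value was 14.84 ± 0.52 in WT, 13.71 ± 0.27 in ERF115OX, 13.48 ± 1.04 in ERF114OX and 9.69 ± 2.54 in ERF115-SRDX. ERF114OX 1 stood at 12.28, apart from the other 2 libraries of its line, and ERF115-SRDX 1, 2 and 3 stood at 8.06, 12.62 and 8.40. A list of stomatal and cuticle genes of the aerial epidermis, drawn up after the photosynthetic values had been seen, was lower by a median log2 of -1.54 in ERF115OX, -1.70 in ERF114OX and -3.26 in ERF115-SRDX, with 10, 11 and 15 of its 16 measured members lower. Casparian strip and endodermis genes, which belong to a root cell layer, had median changes of 0.02, 0.07 and 0.06 (limma called 0, 1 and 2 of 10). The first median was -0.001 under trimmed mean of M-values (TMM) scaling.

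**Figure D2:**
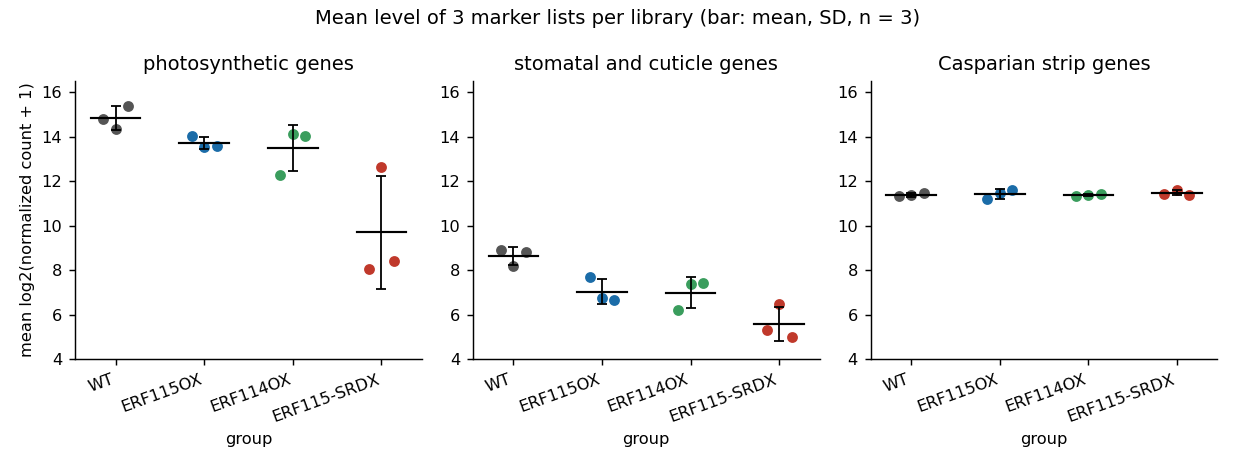
Mean log2 (normalized count + 1) per library of 3 gene lists, photosynthetic genes, stomatal and cuticle genes, and Casparian strip genes, with group mean and SD (n = 3). Photosynthetic genes averaged 14.84 in WT and 9.69 in ERF115-SRDX, where library 2 lay at 12.62, and Casparian strip genes lay between 11.18 and 11.61 in all 12 libraries.

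By camera at its preset correlation, roots overexpressing ERF115 carried more transcript of root hair genes, phytosulfokine genes, class III peroxidases, aquaporins, ribosomal proteins and wound and regeneration regulators than WT, and less of kinesins. Of 18 measured root hair genes, 13 rose and none fell (15 and 0 adjusted over the list alone), with a median log2 change of 0.62. RHS13, a root hair specific gene, went from 1360.0 ± 139.7 in WT to 3518 ± 182 (1.37 ± 0.08, limma adjusted p = 1.3e-06), EXPA18, an expansin that loosens cell walls, rose by 1.25 ± 0.09, and RHS19, a peroxidase, by 1.22 ± 0.08. The largest phytosulfokine change was in PSK5, which encodes a precursor of this sulfated peptide hormone and rose from 289.9 ± 14.6 to 1333 ± 83.6 (4.60-fold, limma adjusted p = 8.7e-09). Of 27 measured kinesins, microtubule motors some of which act in dividing cells, 20 fell and 1 rose (24 and 1 adjusted over the list alone).

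By camera, 12 of the 49 lists and families were called in ERF115OX against WT. The lists above had camera adjusted p = 9.3e-09 for root hair genes, 9.3e-09 for kinesins, 1.2e-05 for ribosomal proteins, 3.7e-05 for peroxidases, 0.00024 for aquaporins, 0.0032 for wound and regeneration regulators and 0.0032 for phytosulfokine genes. With an estimated correlation between members in place of the preset one, the adjusted p of these lists was 0.12 for root hair genes, 0.25 for kinesins, 0.91 for ribosomal proteins, 0.64 for peroxidases, 0.91 for aquaporins, 0.12 for wound regulators and 0.12 for phytosulfokine genes, so that none of these calls held. In all 5 comparisons no list call held with an estimated correlation.

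All 7 measured phytosulfokine genes are given here. PSK1 rose from 552 ± 45.5 to 1028 ± 29.6 normalized counts in ERF115OX, PSK2 from 116 ± 27.6 to 293 ± 1.93 and PSK4 from 2567 ± 424 to 4930.1 ± 803. PSK3 (247 ± 41.4 and 215 ± 17.2) and the receptor genes PSKR1 (3243 ± 238 and 3458 ± 46.9) and PSKR2 (909 ± 29.5 and 982 ± 126) were not called. These 4 calls of 7 were the same in number adjusted over the list alone, with limma adjusted p of 5.6e-05 for PSK1, 0.00043 for PSK2 and 0.00066 for PSK4. Peroxidases rose in 28 and fell in 5 of 63 (30 and 5 adjusted over the list alone, median 0.27). AT5G39580 stood at 711 ± 50.4 in WT and 1707 ± 112 in ERF115OX and RHS18, also root hair specific, at 587 ± 43.7 and 1404 ± 70.5. Aquaporins, the channels for water and small solutes, rose in 20 and fell in 1 of 36 (20 and 1 adjusted over the list alone, median 0.28). PIP2;5 rose from 136 ± 12.2 to 517 ± 92.3 and NIP1;2 from 799 ± 100.1 to 1509.5 ± 92.5. The third member by p, SIP1 (AT5G40390), is annotated as a raffinose synthase and was caught by the name rule of this family. SIP1 rose from 4183 ± 227 to 6170.5 ± 93.4.

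Ribosomal protein genes rose in 68 and fell in 15 of 216 (79 and 15 adjusted over the list alone), by a median of 0.17. Examples were AT1G74270 at 0.54 ± 0.09, AT2G18400 at 0.41 ± 0.07 and AT3G02190 at 0.34 ± 0.06. Among kinesins, whose median was -0.45, AT2G22610 fell from 671 ± 33.8 to 317 ± 32.6 (-1.08 ± 0.10, limma adjusted p = 2.4e-05), AT2G21380 from 2075 ± 168 to 1166 ± 1.72 and AT4G39050 from 3752 ± 156 to 2435 ± 122. Wound and regeneration regulators rose in 9 and fell in 1 of 13 (the same numbers adjusted over the list alone, median 0.25). Weaker list calls were cytokinin response and metabolism (7 higher and 1 lower of 21, 9 and 1 adjusted over the list alone, median 0.22, camera adjusted p = 0.029) and extensins (19 and 4 of 48, both ways of adjusting, camera adjusted p = 0.038). Others were mitotic genes (0 and 6 of 23, both ways, median -0.18, 0.038), auxin biosynthesis (0 and 3 of 7, both ways, median -0.31, 0.041), and phloem and procambium (5 and 2 of 14, 7 and 2 adjusted over the list alone, median 0.29, 0.043). With an estimated correlation their adjusted p was 0.25, 0.91, 0.91, 0.25 and 0.51 in that order. The extensin median was 0.11 while their mean was -0.02, opposite in sign. The last 4 calls were also lost in 4, 4, 6 and 12 of 20 other settings, with highest adjusted p of 0.13, 0.21, 0.13 and 0.097. The cytokinin call was lost with the photosynthetic level of each library as a covariate (0.065), where its median was 0.17.

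Among genes called in ERF115OX with no overlap with WT, the largest rises after ERF115 were mostly in genes nearly silent in WT. AT3G29633, of unknown function, went from 5.22 ± 2.21 to 196 ± 52.6 normalized counts (5.01 ± 0.36, limma adjusted p = 4.6e-06), and AT2G17490, also uncharacterized, from 35.0 ± 9.22 to 887 ± 87.7 (4.65 ± 0.35, adjusted p = 5.8e-06). WRKY66, a WRKY transcription factor gene, had no read in WT and 31.2 ± 7.29 normalized counts in ERF115OX, at least 10.6-fold higher than the floor of 3 reads per library. Its neighbour in TAIR10.1, the AP2/ERF gene AT1G80580, stood at 1.298 ± 1.12 in WT and 34.3 ± 4.76. A further pair of neighbours, AT5G05653 (0.982 ± 0.976 and 44.5 ± 2.90) and AT5G05657, a late embryogenesis abundant family gene (0.650 ± 1.13 and 40.1 ± 1.60), held 3 and 2 reads in WT in all, so no fold is given.

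Of the largest falls in ERF115OX, MRD1 fell from 2024 ± 45.7 to 19.4 ± 6.36 (-6.68 ± 0.19, limma adjusted p = 1.0e-09), and AT1G07887, a non-coding RNA gene next to it in TAIR10.1, from 1984 ± 32.6 to 6.80 ± 3.11. As the strand setting of the counting is not given, these neighbours may share reads. DFR, an enzyme of anthocyanin synthesis, fell from 253 ± 199.7 to 2.36 ± 2.102 (adjusted p = 0.0019), and LDOX, which acts after it, from 107 ± 75.3 to 0.672 ± 1.16 (2 reads in all). Camera called neither the flavonoid list in this line (6 higher and 4 lower of 11, 6 and 5 adjusted over the list alone, median 0.37, adjusted p = 0.75) nor the immune and salicylate list (0 and 3 of 14, both ways of adjusting, 0.46). AT5G44440, a berberine bridge enzyme-like oxidase gene, had 193 ± 151 in WT and no read in ERF115OX, at least 63.2-fold lower by the same floor. LOX2, a chloroplast lipoxygenase of jasmonate synthesis, stood at 527 ± 668 and 5.71 ± 9.89 and AT3G05730, a defensin-like gene, at 1472 ± 497 and 185 ± 317. Both were called by limma (adjusted p = 0.025 and 0.029), with highest adjusted p over the other settings of 0.086 for LOX2 and 0.24 for AT3G05730, the latter in DESeq2.

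Of the other group X ERF genes, the family branch of ERF115 and ERF114, RAP2.6L (ERF113) rose by 0.25 ± 0.08 in ERF115OX (limma adjusted p = 0.031), a call lost under TMM scaling (0.051) and without WT 1, WT 2, ERF115OX 1 or ERF115OX 3 (highest 0.12). ERF108 (525 ± 71.3 in WT, 475 ± 118 in ERF115OX), ERF109 (83.4 ± 7.05 and 82.2 ± 4.96), ERF111 (53.0 ± 10.13 and 44.8 ± 17.3) and ERF112 (1076 ± 51.2 and 1071 ± 52.0) were not called. Of the 7 measured members of this list 2 rose, ERF115 included (2 adjusted over the list alone), and camera did not call the list (adjusted p = 0.56).

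In all, limma called 3839 genes higher and 3660 lower in ERF115OX than in WT at an adjusted p under 0.05. The split depended on scaling, with 3374 higher and 4064 lower under TMM scaling and 4325 and 3352 under quantile normalization. With an absolute log2 change of at least 1 as well, 320 were higher and 662 lower. Photosynthetic genes had a median change of -1.03, with 0 of 19 called by limma. The fit shares 1 spread per gene over all 4 groups. Their mean log2 value had an SD of 2.54 in ERF115-SRDX, against 0.52 in WT and 0.27 in ERF115OX. The lack of calls thus does not show that their level was unchanged. Of the 7499 calls 6827 (91.0%) were also made, in the same direction, with the photosynthetic level as a covariate, an analysis added after the data were seen. That level was 14.34 or more in WT and 14.03 or less in ERF115OX. Without overlap, the covariate cannot exclude shoot content for these calls.

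By camera, again only at the preset correlation, roots overexpressing ERF114 showed higher ribosomal protein, root hair, aquaporin, phloem and procambium, extensin, peroxidase, secondary wall and wound regulator genes than WT, and lower kinesins and ethylene genes. Ribosomal protein genes rose in 132 and fell in 16 of 216 (144 and 18 adjusted over the list alone), by a median of 0.27. Examples were AT2G18400 at 0.55 ± 0.07, AT2G09990 at 0.54 ± 0.08 and AT4G39880 at 0.47 ± 0.07. Root hair genes rose in 15 and fell in none of 18 (16 and 0 adjusted over the list alone, median 0.57). EXPA18 stood at 2342 ± 247 against 1151 ± 83.0 in WT, RHS13 at 2621 ± 185 against 1360.0 ± 139.7 and RHS10, a receptor-like kinase, at 2439.9 ± 108 against 1497 ± 31.9. Kinesins fell in 21 and rose in 1 of 27 (both ways of adjusting, median -0.35). Those with the smallest p were AT2G22610 (-0.93 ± 0.10), AT4G39050 (-0.55 ± 0.06) and AT2G21380 (-0.67 ± 0.08). Aquaporins rose in 18 and fell in 3 of 36 (19 and 3 adjusted over the list alone, median 0.32). PIP2;5 reached 843 ± 122 against 136 ± 12.2 in WT (2.62 ± 0.25, limma adjusted p = 2.0e-05), NIP1;2 1455 ± 86.2 against 799 ± 100.1 and TIP4;1, of the vacuole membrane, 7696 ± 472 against 5366 ± 92.4.

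Phloem and procambium genes rose in 8 and fell in 1 of 14 in ERF114OX (both ways of adjusting, median 0.46). ATHB8, a homeodomain gene marking procambium, rose from 2114 ± 58.0 to 3879.8 ± 116 (0.88 ± 0.05, limma adjusted p = 9.4e-07), PXY, a receptor kinase of the vascular cambium, from 1654 ± 72.0 to 2564 ± 76.9 and DOF2.1, a vascular Dof transcription factor, from 1458 ± 24.1 to 2259 ± 82.2. Ethylene synthesis and response genes fell in 8 and rose in none of 13 (both ways, median -0.43). Secondary wall and xylem genes rose in 7 of 18 and none fell (both ways, median 0.22), and wound and regeneration regulators rose in 7 of 13 and none fell (8 and 1 adjusted over the list alone, median 0.49). Extensins rose in 20 and fell in 6 of 48 (20 and 7 adjusted over the list alone, median 0.29), peroxidases in 26 and 10 of 63 (both ways, median 0.27) and histones in 12 and 2 of 48 (10 and 2 adjusted over the list alone, median 0.11). Phytosulfokine genes rose in 4 and fell in 1 of 7 (4 and 2 adjusted over the list alone), and camera did not call the list (adjusted p = 0.32).

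Camera called 11 of the 49 lists in ERF114OX against WT, with adjusted p = 1.7e-11 for ribosomal proteins, 2.9e-08 for root hair genes, 4.5e-07 for kinesins, 0.0011 for aquaporins, 0.0013 for phloem and procambium, 0.0019 for extensins, 0.0019 for peroxidases, 0.0063 for ethylene genes, 0.0080 for secondary wall genes, 0.011 for wound regulators and 0.023 for histones. With an estimated correlation the adjusted p was 0.82, 0.22, 0.50, 0.82, 0.26, 0.82, 0.82, 0.28, 0.82, 0.26 and 0.85 in that order. The histone call was also lost under quantile normalization (0.075), without WT 3 (0.12) and without ERF114OX 2 (0.11).

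The phytosulfokine genes did not move as one in ERF114OX. PSK5 rose from 289.9 ± 14.6 to 1097 ± 66.8 (1.92 ± 0.08, limma adjusted p = 5.0e-08) and PSK1 from 552 ± 45.5 to 991 ± 97.8. PSK2 fell from 116 ± 27.6 to 40.9 ± 5.24 (-1.45 ± 0.20, adjusted p = 0.00023). PSKR2 rose by 0.29 ± 0.08 and PSK4 by 0.41 ± 0.15 (limma adjusted p = 0.045). The PSK4 call was lost in 8 other settings (highest 0.18). PSK3 (219 ± 38.2) was not called, and neither was PSKR1 (2890.0 ± 127; adjusted p = 0.061), which passed in 5 other settings (lowest 0.020). None of the other group X ERF genes was called. ERF108 stood at 433 ± 38.0 normalized counts, ERF109 at 69.6 ± 6.59, ERF111 at 37.6 ± 11.4, ERF112 at 1176 ± 189 and RAP2.6L at 1199.6 ± 112 (limma adjusted p between 0.17 and 0.35 for all 5).

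Single genes with the largest rises in ERF114OX, after ERF114, were AT1G08943, from 3.93 ± 1.96 in WT to 107 ± 21.6, and AT3G29633, from 5.22 ± 2.21 to 132 ± 15.4. SBT3.3, a subtilisin-like protease known from immune priming, rose from 35.3 ± 5.43 to 443 ± 13.2 (3.62 ± 0.18, limma adjusted p = 2.6e-07), and DIR5, a dirigent protein gene, from 4.59 ± 2.29 to 56.4 ± 8.39. RTFL4, a small plant peptide gene of the ROTUNDIFOLIA-like family, rose from 2.63 ± 2.28 to 30.1 ± 9.07 and the peroxidase AT1G49570 from 11.8 ± 10.3 to 94.5 ± 21.5. Among the largest falls, CYP79F1, which starts the synthesis of aliphatic glucosinolates, dropped from 134 ± 94.0 to 1.35 ± 1.17 (-5.80 ± 0.59, limma adjusted p = 3.6e-05). DFR dropped from 253 ± 199.7 to 2.04 ± 0.0949 and AT5G44440 from 193 ± 151 to 1.74 ± 2.16. The neighbours AT3G02670, a glycine-rich protein gene, and AT3G02673 fell from 297 ± 128 to 6.01 ± 3.79 and from 107 ± 40.2 to 2.38 ± 1.59. AT5G09370, a lipid transfer family gene (73.1 ± 19.7 in WT), and the F-box gene MEO (66.9 ± 26.9 in WT) had no read in ERF114OX, at least 23.9-fold and 21.8-fold lower by the floor of 3 reads per library.

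In all, limma called 4093 genes higher and 4581 lower in ERF114OX than in WT (47.2% higher). The split was 5136 higher and 3724 lower (58.0% higher) under quantile normalization and 3384 and 5213 under TMM scaling. With an absolute log2 change of at least 1 as well, 281 were higher and 1130 lower. Photosynthetic genes had a median change of -1.37, with 0 of 19 called by limma. Here too the spread is shared with ERF115-SRDX, where their mean log2 value had an SD of 2.54, against 1.04 in ERF114OX. The lack of calls does not show that their level was unchanged. With the photosynthetic level as a covariate, 7581 (87.4%) of the 8674 calls were also made in the same direction. As that level was 14.34 or more in WT and 14.11 or less in ERF114OX, the covariate cannot exclude shoot content here either.

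The overexpressors shared much of their change from WT. Of the genes tested, 2701 were called higher in both and 2658 lower in both, while 54 were called in opposite directions. The even split depended on scaling, with 2223 higher and 3047 lower under TMM scaling and 3170 and 2291 under quantile normalization. XTH20, a xyloglucan endotransglucosylase that remodels primary cell walls, rose 12.8-fold in ERF115OX and 8.46-fold in ERF114OX, from 592 ± 145 in WT to 7569.6 ± 129 and 5012 ± 60.9 (3.70 ± 0.13 and 3.11 ± 0.13, limma adjusted p = 8.7e-09 and 7.2e-08). AT3G29633, WRKY66 and RTFL4 were higher in both lines as well, WRKY66 at 10.4 ± 4.66 in ERF114OX, at least 3.53-fold above the floor, and RTFL4 at 25.2 ± 7.89 in ERF115OX. So was KCO3, of the potassium channel family, at 17.0 ± 2.90 and 18.3 ± 7.96 against 0.664 ± 1.15 in WT (2 reads in all). Lower in both were DFR, LDOX, AT5G44440, the F-box gene AT3G59250 (92.3 ± 63.7 in WT, 2.04 ± 0.0261 in ERF115OX and 5.20 ± 7.25 in ERF114OX) and CRK30, a cysteine-rich receptor-like kinase (129.8 ± 54.5, 8.42 ± 10.2 and 4.90 ± 4.39). LDOX stood at 5.56 ± 6.33 in ERF114OX, where its call (limma adjusted p = 0.024) was lost in 5 other settings, DESeq2 among them (highest 0.088). Limma also called AT5G44440, AT3G59250, CRK30 and LDOX lower in ERF115-SRDX than in WT (-6.37, -6.33, -6.17 and -3.51, adjusted p at most 0.043). KCO3 was called higher there too (2.95, limma adjusted p = 0.00096), so these changes were not particular to the overexpressors. DFR, AT3G29633, WRKY66 and RTFL4 were not called in ERF115-SRDX, and XTH20 was called lower (-0.39, limma adjusted p = 0.023).

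If the calls of each line fell on genes independently, 672 would be higher in both, 717 lower in both, 752 higher in ERF115OX and lower in ERF114OX, and 641 the reverse. In 100 simulations of unchanged groups compared with the same WT libraries, no gene was called in both. Unchanged genes are seldom called by design, so that count does not measure what shared WT libraries add to the overlap. Across genes, which are not independent replicates, the log2 changes had a correlation of 0.758 (0.499 simulated) and a covariance of 0.255 (0.0281 simulated, a difference of 0.227). The 3 WT libraries are too few to split, and part of the excess may come from the shared controls. Photosynthetic and stomatal and cuticle genes were lower than WT in both lines, so a shared difference in shoot content may add to the excess too. With the photosynthetic level as a covariate 5191 genes were shared. That level did not overlap between WT and either line, so this count cannot exclude shoot content. With an absolute log2 change of at least 1, 676 genes were shared, 177 higher and 499 lower.

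**Figure D3:**
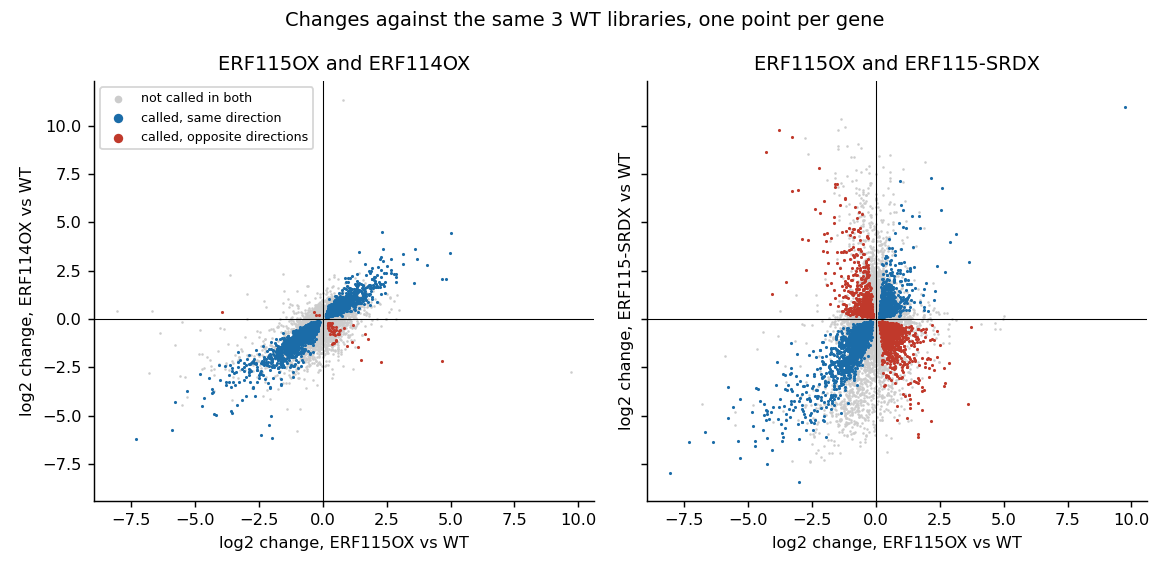
Log2 change against WT of each gene tested, ERF115OX on the horizontal axis against ERF114OX (left) or ERF115-SRDX (right) on the vertical axis, with genes called in the same direction in blue and in opposite directions in red. The left panel holds 5359 genes called the same way and 54 opposite, the right panel 2662 and 1972.

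The overexpressors were compared directly as well. ERF115OX had higher PSK2 than ERF114OX (293 ± 1.93 against 40.9 ± 5.24, 2.82 ± 0.20, limma adjusted p = 2.1e-05). AT2G17490 stood at 887 ± 87.7 in ERF115OX and 7.23 ± 2.94 in ERF114OX (6.82 ± 0.35, limma adjusted p = 1.0e-06). CYP79F1 stood at 57.4 ± 9.43 and 1.35 ± 1.17, PDF1.4, a defensin-like gene, at 126 ± 22.9 and 5.52 ± 4.36, and VIM5, of a family that binds methylated DNA, at 29.5 ± 11.7 and 1.40 ± 1.21. Lower in ERF115OX than in ERF114OX were MRD1 (19.4 ± 6.36 against 2706 ± 197), AT1G07887 (6.80 ± 3.11 against 2678 ± 204) and HEI10, a RING protein of meiotic crossing over that lies next to them (145 ± 5.47 against 2830.3 ± 171). AT3G16670, an Ole e 1 and extensin family gene, was called lower too (41.6 ± 72.1 against 336 ± 169.8, limma adjusted p = 0.045), a call lost in 11 other settings, DESeq2 among them (0.50).

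Of 197 cytochrome P450 genes 38 were higher and 3 lower in ERF115OX than in ERF114OX (53 and 11 adjusted over the list alone, median 0.16, camera adjusted p = 0.00093). Of 28 xyloglucan endotransglucosylases 8 and 1 were (11 and 1 adjusted over the list alone, camera adjusted p = 0.018), and of 21 cytokinin genes 5 and 0 (6 and 0 adjusted over the list alone, 0.020). Of 13 ethylene genes 3 and 0 were higher and lower (both ways of adjusting, camera adjusted p = 0.018) and of 7 phytosulfokine genes 4 and 0 (4 and 1 adjusted over the list alone, 0.020). Of 7 auxin biosynthesis genes 0 were higher and 3 lower (0 and 4 adjusted over the list alone, median -0.27, camera adjusted p = 0.00093). Of 16 G1 to S phase genes 0 and 2 were higher and lower (0 and 8 adjusted over the list alone, median -0.16, 0.00032) and of 14 phloem and procambium genes 0 and 2 (0 and 3 adjusted over the list alone, 0.00545). For 23 mitotic genes (median -0.15, 0.0014) and 216 ribosomal protein genes (median -0.09, 5.3e-05) camera called a shift downwards though limma called 0 and 2 single members. Their adjusted p with an estimated correlation was 0.66 for P450 genes, 0.72 for xyloglucan endotransglucosylases and 0.28 for cytokinin, ethylene, phytosulfokine and phloem genes. It was 0.165 for auxin biosynthesis, 0.66 for G1 to S phase, 0.78 for mitotic and 0.78 for ribosomal genes.

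The other 5 of the 15 lists called by camera between the overexpressors were WRKY factors (6 higher and 0 lower of 61, 14 and 1 adjusted over the list alone), NAC factors (8 and 2 of 75, 13 and 4 adjusted over the list alone), tau glutathione S-transferases (6 and 1 of 25, both ways of adjusting), auxin response (5 and 1 of 20, 7 and 1 adjusted over the list alone) and secondary wall and xylem (0 and 2 of 18, 0 and 3 adjusted over the list alone). Their camera adjusted p was 0.018, 0.018, 0.024, 0.026 and 0.027, and the adjusted p was 0.78, 0.78, 0.78, 0.28 and 0.78 with an estimated correlation. The calls of these 5 lists and of xyloglucan endotransglucosylases, cytokinin, ethylene and phytosulfokine genes were each lost without at least 1 of the libraries ERF115OX 1, 2 or 3 or ERF114OX 1, 2 or 3. The phytosulfokine call was lost without ERF115OX 1 (0.061) or ERF114OX 2 (0.052) and the secondary wall call without ERF115OX 1 (0.59).

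In all, limma called 1116 genes higher and 497 lower in ERF115OX than in ERF114OX, and 249 and 33 with an absolute log2 change of at least 1. The total of 1613 depended on single libraries, at 600 without ERF115OX 2, 887 without ERF115OX 3, 841 without ERF114OX 2 and 922 without ERF114OX 3. It was 917 when only these 2 groups were fitted. Of the phytosulfokine genes besides PSK2, PSK4 (0.53 ± 0.15, limma adjusted p = 0.048), PSK5 (0.28 ± 0.08, 0.045) and PSKR1 (0.26 ± 0.06, 0.031) were called higher in ERF115OX, with highest adjusted p over the other settings of 0.204, 0.195 and 0.116. RAP2.6L was called higher as well (0.38 ± 0.08, 0.015, highest 0.062).

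At the preset correlation of camera, roots with ERF115-SRDX carried higher transcripts of oxidative and xenobiotic stress, immune and salicylate, tau glutathione S-transferase and heat shock genes than WT, and far lower photosynthetic genes. Of 14 oxidative and xenobiotic stress genes 12 rose and 1 fell (both ways of adjusting, median 1.22). CYP81D8, a P450 induced by many toxic compounds, rose 24.2-fold from 682 ± 54.5 to 16526 ± 1519.5 (4.60 ± 0.08, limma adjusted p = 7.3e-12). ZAT12, a zinc finger regulator, rose from 718 ± 22.4 to 4992 ± 326 and GSTU4 from 248 ± 13.8 to 2089 ± 95.8. Of 14 immune and salicylate genes 11 rose and 1 fell (both ways, median 1.92). PAD3, which makes the phytoalexin camalexin, rose 63.3-fold from 599.7 ± 66.0 to 37952 ± 3472 (5.98 ± 0.17, limma adjusted p = 7.9e-11). WRKY33, a regulator of that pathway, rose from 1854 ± 129.8 to 10074 ± 355 and CYP71A12, an enzyme of indolic defence compounds, from 472 ± 239 to 84348 ± 9805. CYP71A12 has the near-identical copy CYP71A13, and reads of the pair can be split wrongly. Of 25 tau glutathione S-transferases 18 rose and 5 fell (18 and 6 adjusted over the list alone, median 0.90). GSTU10 rose from 695 ± 66.9 to 12555 ± 649.9 and GSTU22 from 6881 ± 722 to 19264 ± 809.

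Of 67 heat shock protein genes 34 rose and 4 fell in ERF115-SRDX (both ways of adjusting, median 0.21). Hsp70-2 rose from 1445 ± 255 to 7069 ± 793, and the small heat shock protein genes AT2G29500, from 928 ± 68.5 to 4164 ± 415, and AT5G51440, from 581 ± 8.78 to 1701 ± 205. All 19 photosynthetic genes fell (both ways, median -5.25). The 95% bootstrap interval was -5.78 to -4.59, drawn over members, whose estimated correlation was 0.97. It leaves out the spread between the ERF115-SRDX libraries, whose mean log2 values were 8.06, 12.62 and 8.40. RCA, the Rubisco activase, stood at 93669 ± 37063 in WT and 5628 ± 7066 in ERF115-SRDX, LHCB4.1, a light-harvesting protein, at 34696 ± 12683 and 2485 ± 2871 and PSBR, of photosystem II, at 20808 ± 6818 and 2566 ± 1986. Lipid transfer protein genes fell in 41 and rose in 15 of 76 (41 and 16 adjusted over the list alone, median -0.78), and aquaporins fell in 24 and rose in 10 of 36 (both ways, median -0.57). Phloem and procambium genes fell in 8 of 14 and none rose (both ways, median -0.34), and histones rose in 20 and fell in 5 of 48 (both ways, median 0.16). Root hair genes, with 1 higher and 5 lower of 18 (1 and 4 adjusted over the list alone, median -0.08), were not called as a list (camera adjusted p = 0.56).

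Camera called 9 of the 49 lists in ERF115-SRDX against WT, at adjusted p = 1.3e-06 for oxidative stress, 5.3e-05 for photosynthetic, 8.7e-05 for immune, 0.00020 for tau glutathione S-transferase, 0.00058 for heat shock, 0.024 for lipid transfer, 0.028 for aquaporin, 0.028 for histone and 0.034 for phloem genes. With an estimated correlation the adjusted p was 0.69, 0.92, 0.69, 0.89, 0.69, 0.92, 0.92, 0.92 and 0.70 in that order. With the photosynthetic level as a covariate 4 calls ended: the photosynthetic list itself (0.52), lipid transfer (0.40), aquaporins (0.26) and histones (0.23). The median ± SD over members went from -5.25 ± 1.005 to -0.15 ± 0.84, -0.78 ± 1.93 to -0.24 ± 1.72, -0.57 ± 1.004 to -0.36 ± 0.90 and 0.156 ± 0.397 to 0.154 ± 0.328 in that order. The histone median thus stayed where it was and its call ended all the same. The covariate is the mean of the photosynthetic list, so the end of that list's own call was fixed in advance. The lipid transfer and aquaporin calls also ended with ERF115-SRDX 2 as the only library of its line (0.057 and 0.084). Histones were also lost in 4 and phloem genes in 4 other settings (highest 0.12 and 0.061).

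Several genes went from near silence in WT to high levels in ERF115-SRDX. PNP-A, a small secreted peptide gene, rose from 37.7 ± 53.6 to 15390.0 ± 1559.9 normalized counts (9.78 ± 0.82, limma adjusted p = 7.6e-07), and WAK3, a wall-associated kinase, from 11.3 ± 19.6 to 4353 ± 764. AT2G29250, a lectin receptor kinase gene, rose from 7.97 ± 13.8 to 2911 ± 287, AT3G55790 from 7.62 ± 11.6 to 3588 ± 442, AT1G55230 from 29.4 ± 39.5 to 9566 ± 953 and AT1G51920 from 14.6 ± 18.9 to 4596 ± 394. The largest falls were GER3, a germin-like protein gene (2274 ± 1524 in WT and 9.60 ± 10.5), AT1G07887 (1984 ± 32.6 and 8.82 ± 7.08), and the lipase genes LTL1 (1376 ± 458 and 27.8 ± 44.7) and AT4G28780 (730.0 ± 325 and 23.7 ± 41.0). Next came the lipid transfer family gene AT2G10940 (17171 ± 5865 and 458 ± 747), LHB1B1, a light-harvesting protein with near-identical copies (28805 ± 11777 and 1002 ± 1655), and AT5G15780 (1256 ± 575 and 18.6 ± 25.8). With the photosynthetic level as a covariate, the calls of LTL1, AT2G10940, AT4G28780, LHB1B1 and AT5G15780 ended (limma adjusted p = 0.787, 0.0925, 0.692, 0.997 and 0.174), and those of GER3 and AT1G07887 held (0.021 and 1.1e-05). LHB1B1 is of the kind of gene whose mean is the covariate, so the end of its call was near certain in advance. The changes shrank from -7.49 ± 1.39 to -0.51 ± 1.08 for LTL1, -7.41 ± 1.19 to -0.88 ± 0.36 for AT2G10940 and -7.37 ± 1.298 to -0.44 ± 0.66 for AT4G28780, and from -7.36 ± 1.35 to -0.004 ± 0.506 for LHB1B1 and -7.27 ± 1.105 to -2.02 ± 1.02 for AT5G15780.

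The phytosulfokine genes split in ERF115-SRDX. PSKR1 rose from 3243 ± 238 to 9967 ± 659 (1.62 ± 0.06, limma adjusted p = 8.7e-10) and PSK4 from 2567 ± 424 to 5555 ± 437. PSK1 fell from 552 ± 45.5 to 186 ± 16.8 (-1.57 ± 0.09, adjusted p = 3.9e-08) and PSK5 from 289.9 ± 14.6 to 143 ± 1.53 (-1.01 ± 0.08). The PSK5 value of ERF115-SRDX 3, at 145.0948, is the only value of the table that is not a whole number of reads divided by its size factor. PSK2 (75.9 ± 13.8, adjusted p = 0.026) and PSK3 (324 ± 35.0, adjusted p = 0.044) were called lower and higher, with highest adjusted p over the other settings of 0.55 and 0.16. Under the photosynthetic covariate PSK2 went from -0.59 ± 0.20 to -0.36 ± 0.38 and PSK3 from 0.39 ± 0.15 to 0.73 ± 0.27 (0.058), and neither was called. PSKR2 (889 ± 12.2) was not called. With 3 higher and 3 lower of 7 (both ways of adjusting), camera did not call the list (adjusted p = 0.93). Of the group X genes, ERF108 fell from 525 ± 71.3 to 189 ± 4.19 and RAP2.6L rose from 1309.7 ± 84.6 to 2617 ± 161 (-1.46 ± 0.16 and 1.00 ± 0.08, adjusted p = 9.8e-06 and 4.7e-07). ERF109 (95.2 ± 4.15, adjusted p = 0.29), ERF111 (62.6 ± 8.99, 0.55), ERF112 (1233 ± 56.5, 0.10) and ERF114 (0.92) were not called by limma. ERF109 passed under quantile normalization (0.040). ERF112 passed when only these 2 groups were fitted (0.031) and without ERF114OX 1 and ERF115-SRDX 2 together (0.036).

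In all, limma called 5478 genes higher and 6229 lower in ERF115-SRDX than in WT, and 1476 and 2599 with an absolute log2 change of at least 1. Under quantile normalization 6223 were higher and 5570 lower. The first principal component, with 67% of the variance, set the 3 ERF115-SRDX libraries apart from the others. The total of 11707 was 6092 with the photosynthetic level as a covariate, where 5875 (50.2%) of the calls were made again in the same direction. Of the calls 8152 were made again with ERF115-SRDX 2, the library with the highest photosynthetic level of its line, as the only library of that line. Both settings were added after the data were seen. The photosynthetic level was 14.34 or more in WT and 12.62 or less in ERF115-SRDX, so the covariate cannot separate shoot content from genotype.

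**Figure D4:**
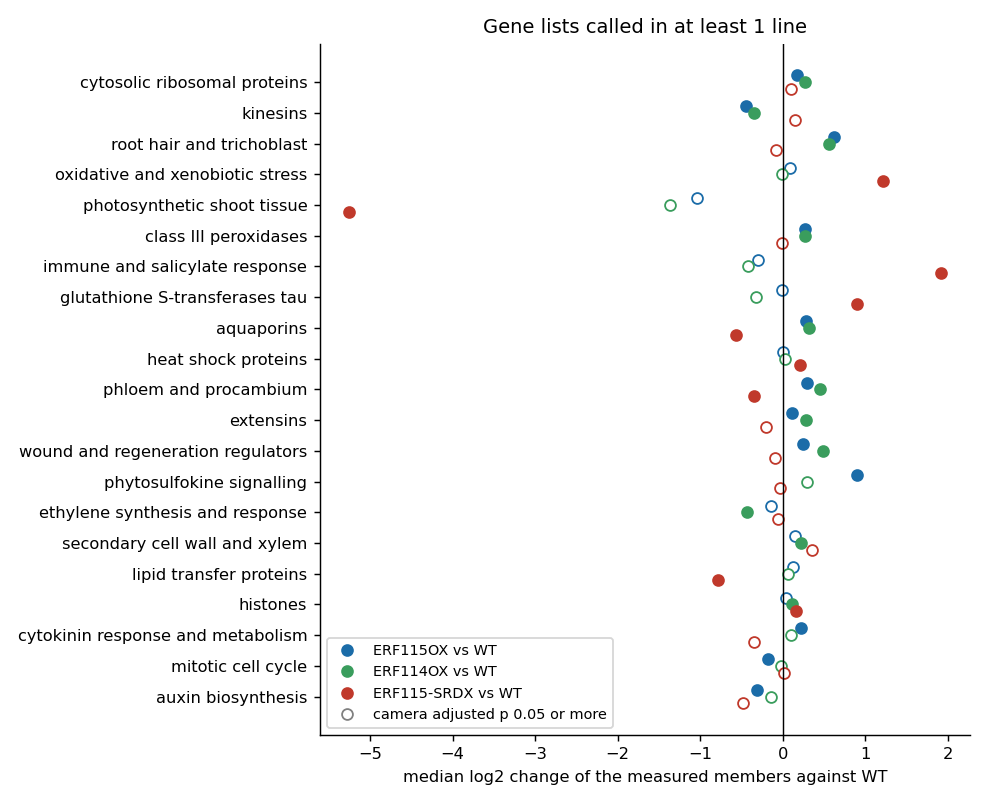
Median log2 change against WT of the members of each gene list or family called in at least 1 of the 3 lines, with filled points where camera gave an adjusted p under 0.05. The photosynthetic median was -5.25 in ERF115-SRDX, the immune and salicylate median 1.92 in ERF115-SRDX, and the root hair median 0.62 in ERF115OX and 0.57 in ERF114OX.

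ERF115 was higher than WT in both ERF115OX and ERF115-SRDX, and the question was whether the construct with the repression motif moved genes the other way. Of the genes tested, 1109 were higher in ERF115OX and lower in ERF115-SRDX than in WT, 863 the reverse, 1170 higher in both and 1492 lower in both. Independent lists of these sizes would give 1023, 857.7, 899.7 and 975.3. The split of the shared calls depended on scaling, with 958 higher and 1660 lower under TMM scaling and 1466 and 1428 under quantile normalization. With an absolute log2 change of at least 1 in both, 43 were higher and 441 lower. FMO1, a monooxygenase of systemic immunity, fell 10.5-fold in ERF115OX and rose 102-fold in ERF115-SRDX (74.9 ± 9.99 in WT, 7.16 ± 3.15 and 7627 ± 1175; limma adjusted p = 7.9e-06 and 7.9e-10). PSK1 and PSK5 rose in ERF115OX and fell in ERF115-SRDX, PSK5 standing at 1333 ± 83.6 and 143 ± 1.53 (3.21 ± 0.08 between the lines, adjusted p = 1.3e-11).

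Higher in ERF115OX and lower in ERF115-SRDX by the same measure were M17, a late embryogenesis abundant gene (53.4 ± 54.9 in WT, 477 ± 107 and 1.03 ± 1.04), the defensin-like genes AT4G11393 (13.7 ± 3.88, 93.1 ± 20.02 and 0.696 ± 1.21) and AT5G33355 (10.8 ± 5.62, 69.0 ± 12.003 and no read). So were AT4G00130 (10.9 ± 14.1, 35.3 ± 6.54 and no read) and the receptor kinase gene AT3G46370 (6.21 ± 1.45, 52.2 ± 17.0 and 0.672 ± 1.16). The falls of M17, AT4G11393, AT4G00130 and AT3G46370 in ERF115-SRDX were not called with the photosynthetic level as a covariate (limma adjusted p = 0.074, 0.089, 0.35 and 0.053). Their changes went from -4.41 ± 0.65 to -2.68 ± 1.03, -3.30 ± 0.45 to -1.76 ± 0.72, -2.53 ± 0.89 to -2.32 ± 1.64 and -2.30 ± 0.51 to -2.75 ± 0.98, so the SE grew for all 4 while the change shrank clearly for M17 and AT4G11393 only. The fall of AT4G00130 was also lost in 9 more settings and that of AT3G46370 under quantile normalization (0.27). The rise of AT4G00130 in ERF115OX was lost in 9 other settings (highest 0.11). Lower in ERF115OX and higher in ERF115-SRDX, besides FMO1, were AT2G29220, a lectin receptor kinase gene (37.2 ± 32.2 in WT, 0.672 ± 1.16 and 11404 ± 929), and PNP-A (0.344 ± 0.596 in ERF115OX), AT1G55230 (0.672 ± 1.16 in ERF115OX) and AT2G04070, a MATE transporter gene (40.3 ± 9.30, 4.44 ± 3.35 and 4121 ± 466). In WT the SD of PNP-A (37.7 ± 53.6) and AT1G55230 (29.4 ± 39.5) was above the mean, and that of AT2G29220 near it. The sizes of these falls in ERF115OX thus rest on widely differing WT libraries, unlike those of FMO1 and AT2G04070. The call of AT1G55230 in ERF115OX (limma adjusted p = 0.013) was lost when only ERF115OX and WT were fitted (0.054).

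In the direct contrast, the genes highest in ERF115OX relative to ERF115-SRDX were M17, AT3G59930, a defensin-like gene (5178 ± 923 against 22.6 ± 2.71, 7.77 ± 0.16, limma adjusted p = 6.9e-12), and AT4G07820, of the CAP family of secreted proteins (406 ± 58.9 against 1.37 ± 1.19). Next were RAP2.9, an AP2/ERF gene (370.3 ± 53.7 against 1.37 ± 1.19), and EARLI1, a lipid transfer family gene (2816 ± 179 against 24.2 ± 18.9). The lowest were PNP-A, AT2G29220, AT1G55230, AT1G51920, which had no read in ERF115OX and was at least 1503-fold lower by the floor of 3 reads per library, and WAK3 (0.339 ± 0.587 against 4353 ± 764). ERF108 was higher in ERF115OX (1.29 ± 0.16, adjusted p = 2.5e-05) and RAP2.6L lower (-0.75 ± 0.08, adjusted p = 5.0e-06) by limma. PSK1 and PSK2 were higher (2.47 ± 0.09 and 1.95 ± 0.20), PSKR1 and PSK3 lower (-1.52 ± 0.06 and -0.58 ± 0.15). ERF115 (-1.22 ± 1.14, 0.39), ERF114 (0.63 ± 1.02, 0.63), ERF109 (0.23), ERF111 (0.16), ERF112 (0.085), PSK4 (0.31) and PSKR2 (0.16) were not called by limma. ERF114 passed without ERF115OX 1 (adjusted p = 0.00051) and PSKR2 without ERF115OX 3 (0.018). ERF112 passed when only these 2 groups were fitted (0.0275) and without ERF114OX 1 and ERF115-SRDX 2 together (0.028). With only these 2 groups ERF115 passed as well (1.6e-06), in a fit without the widely differing WT values.

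Camera called 12 lists between ERF115OX and ERF115-SRDX. Higher in ERF115OX were root hair genes (15 higher and 1 lower of 18, both ways of adjusting, median 0.78, camera adjusted p = 0.00010), aquaporins (23 and 5 of 36, 24 and 5 adjusted over the list alone, median 0.87, 0.00083) and photosynthetic genes (19 and 0 of 19, both ways, median 3.98, 0.00099). So were lipid transfer proteins (43 and 12 of 76, 45 and 14 adjusted over the list alone, median 0.95, camera adjusted p = 0.0042), phloem and procambium (10 and 2 of 14, both ways, median 0.55, 0.0074), cytokinin genes (11 and 2 of 21, both ways, median 0.33, 0.018) and extensins (25 and 8 of 48, both ways, median 0.42, 0.048). Lower in ERF115OX were kinesins (2 higher and 21 lower of 27, 2 and 22 adjusted over the list alone, median -0.62, 1.6e-05), oxidative and xenobiotic stress (2 and 11 of 14, both ways, median -1.35, 3.4e-05) and immune and salicylate genes (1 and 10 of 14, both ways, median -2.18, 0.00010). So were tau glutathione S-transferases (5 and 17 of 25, both ways, median -0.77, camera adjusted p = 0.00083) and heat shock proteins (5 and 38 of 67, 6 and 38 adjusted over the list alone, median -0.26, 0.0011). Their adjusted p with an estimated correlation was 0.41 for root hair, heat shock, phloem and cytokinin genes, 0.48 for kinesins and oxidative stress, 0.45 for immune genes and 0.73 for the other 5 lists. The photosynthetic, lipid transfer and extensin calls were lost with the photosynthetic level as a covariate (0.42, 0.095 and 0.40), with medians of 0.22, 0.25 and 0.22. For the photosynthetic list, whose mean is the covariate, that loss was fixed in advance. The photosynthetic call was also lost without ERF115-SRDX 1 and 3 together (0.073), and the extensin call in 8 more settings (highest 0.19).

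In all, limma called 6928 genes higher and 6169 lower in ERF115OX than in ERF115-SRDX, and 2483 and 1695 with an absolute log2 change of at least 1. With the photosynthetic level as a covariate the total of 13097 was 8221 and the 1972 opposite calls against WT were 1022. The 2662 calls in the same direction fell as well, to 1633. In 100 simulations of unchanged groups against the same WT libraries, none were called in opposite directions and at most 1 in the same direction. As unchanged genes are seldom called by design, these counts do not measure what the shared WT libraries add. Across genes the log2 changes of the 2 lines had a correlation of 0.275 (-0.225 from the simulated mean) and a covariance of 0.193 (0.0280 simulated, a difference of 0.165). The WT libraries are too few to split here too, and part of the excess of shared calls over independent lists may come from the shared controls. Photosynthetic and stomatal and cuticle genes were lower than WT in both of these lines as well. Shoot content may thus add to that excess, which was not tested. The opposite calls were 159 with an absolute log2 change of at least 1 in both and 1285 with ERF115-SRDX 2 as the only library of its line.

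**Figure D5:**
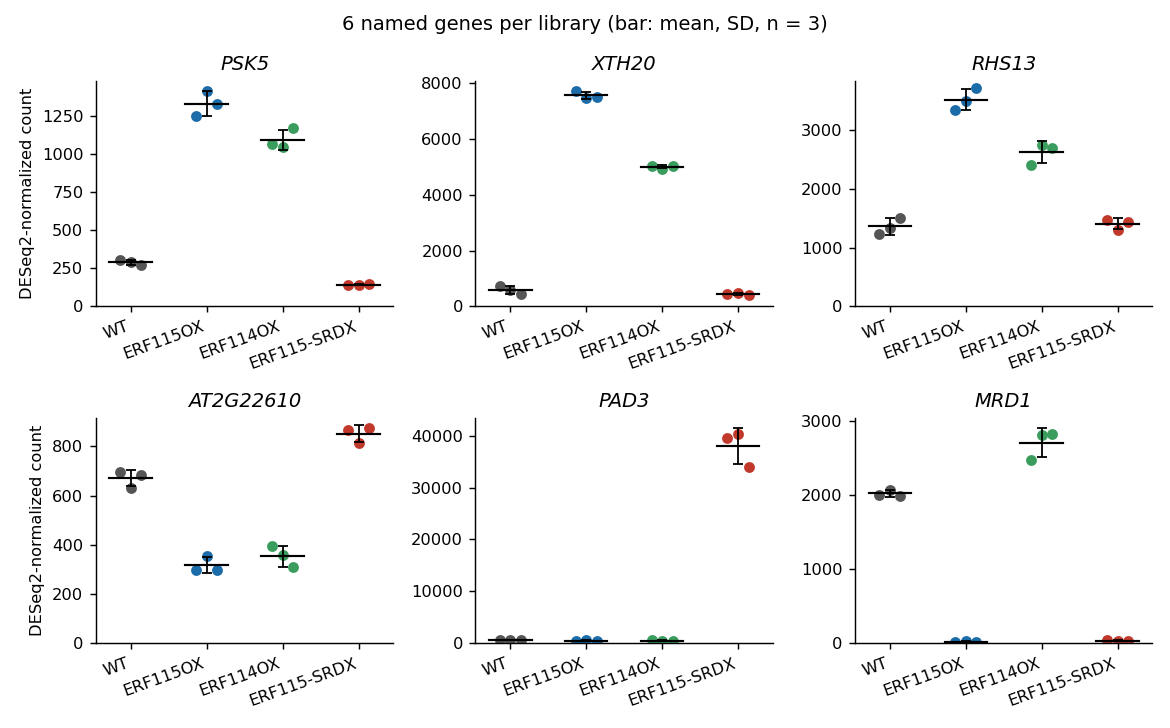
Normalized counts of PSK5, XTH20, RHS13, AT2G22610, PAD3 and MRD1 in each library, with group mean and SD (n = 3). PSK5 averaged 1333 in ERF115OX and 143 in ERF115-SRDX against 289.9 in WT, PAD3 averaged 37952 in ERF115-SRDX against 599.7 in WT, and MRD1 averaged 19.4 in ERF115OX and 34.4 in ERF115-SRDX against 2024 in WT.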

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

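The tests of depth, of the immune genes against shoot content and both tests of the root hair genes were chosen only after the result was seen. The list of stomatal and cuticle genes was written after the photosynthetic values and before its own values were seen.

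ERF115OX and ERF114OX differed in the direct contrast in 1613 genes (limma). All 54 genes called in opposite directions against WT in these lines also differed in that contrast. That was near certain in advance, since in the same fit the direct difference adds the 2 opposite changes. In ERF115OX and ERF115-SRDX, 1972 genes were called in opposite directions against WT, 1109 and 863 by direction, near the 1023 and 857.7 that independent lists give. Aquaporins differed between ERF115OX and ERF115-SRDX by a median log2 of 0.87, with calls in opposite directions against WT. The ERF115-SRDX call of aquaporins ended with the photosynthetic level as a covariate (0.26) and with ERF115-SRDX 2 as the only library of its line (0.084), a fit from fewer samples. With the covariate the median ± SD over members went from -0.57 ± 1.004 to -0.36 ± 0.90, with 13 of 36 still called lower and 8 higher, so the lost call does not show that the change went away. Phloem and procambium genes differed between these lines by a median log2 of 0.55, again with opposite calls against WT. The ERF115OX call of this list was lost in 12 of 20 other settings (highest 0.097) and the ERF115-SRDX call in 4 (highest 0.061).

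Photosynthetic genes were lower in ERF115-SRDX than in WT by a median log2 of -5.25. The ratio of mean reads was 1.003, so depth did not differ. Values were also divided by size factors, so this says nothing of other differences between libraries. Stomatal and cuticle genes, which carry out no photosynthesis, were lower too, by a median of -3.26. The 95% bootstrap interval, over members and not libraries, was -4.22 to -1.58. Less shoot tissue in these libraries is thus a candidate explanation. Lower expression in root cells cannot be told apart from less shoot tissue, because both lists fell and the photosynthetic list fell further (-5.25). The further fall lay in ERF115-SRDX 1 and 3, with mean log2 values of 8.061 and 8.399 for photosynthetic and 5.284 and 4.981 for stomatal and cuticle genes. In ERF115-SRDX 2, at 12.617 and 6.464, the lists lay about equally far below WT (14.341 to 15.386 and 8.168 to 8.902).

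Immune and salicylate genes were higher in ERF115-SRDX than in WT by a median log2 of 1.92. With the photosynthetic level as a covariate the median was 1.58. That level was 14.34 or more in WT and 12.62 or less in ERF115-SRDX. As these did not overlap, the covariate cannot separate shoot content from genotype. Leaving out each ERF115-SRDX library in turn gave a highest camera adjusted p of 0.00014, which argues against a single library. An effect of the construct may remain as a hypothesis, found and tested on the same data, and a difference in growth or handling of the line was not tested.

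Root hair genes were higher in both overexpressors. A larger root share of the RNA would raise genes of other root cells alike. The upper bound of the Casparian strip median, bootstrapped over members and not libraries, was at most 0.18 against root hair medians of 0.62 and 0.57. Other lists were mixed. In ERF115OX and ERF114OX, medians were 0.05 and -0.03 for suberin genes, and -0.02 and 0.26 for root cap genes. Phloem and procambium genes stood at 0.29 and 0.46, so these lists do not settle a larger root share. With the photosynthetic level as a covariate the camera adjusted p at the preset correlation was at most 6.9e-08, with medians of 0.65 and 0.60. That level was 14.34 or more in WT and 14.11 or less in these lines. Without overlap, the covariate cannot exclude shoot content. More root hair cells or a change within them may each account for the rise, and these tests (0.18 and 6.9e-08) do not separate them.

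Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05, and in each of them 1 split, the real one, gave a result as large. Fitted on only the groups compared, the real splits called 6564 genes for ERF115OX against WT, 7844 for ERF114OX against WT, 11521 for ERF115-SRDX against WT, 917 for ERF115OX against ERF114OX and 12776 for ERF115OX against ERF115-SRDX. The highest other splits called 25 genes between ERF115OX and ERF114OX and 0 in the other comparisons. For calls shared by the overexpressors, 1 of 100 splits drawn from 9 libraries, the real one with 4984, gave as many, and the highest other gave 4246. For opposite calls of ERF115OX and ERF115-SRDX, 1 of 100 splits, the real one with 1955, gave as many, and the highest other gave 0. Whether chance can be excluded for either cannot be told from these counts, because a split that mixes WT with a line loses most calls of that line. Splits that mixed WT reached at most 401 shared calls, and only 2 of the other splits for the shared calls, and 0 for the opposite calls, kept WT apart.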

How the results depend on the processing

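The settings with the photosynthetic covariate, with ERF114OX 1 and ERF115-SRDX 2 left out together, and with ERF115-SRDX 1 and 3 left out together were chosen after the data were seen, as was the fit of only the groups compared for genes; all others were planned. For the totals and the transgenes, 246 values kept their direction and lay within 1.5 times of the reported count or kept their call, and 24 moved further. For named genes, 3500 values kept direction and call, 148 lost a call, 17 gained one and 31 turned sign. None of the 161 called gene results turned sign in any setting; 23 lost a call in at least 1 setting other than the fold threshold.

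An absolute log2 change of at least 1 left 982 genes for ERF115OX against WT, 1411 for ERF114OX, 4075 for ERF115-SRDX, 282 between the overexpressors, 4178 between ERF115OX and ERF115-SRDX, 676 shared and 159 opposite calls, since it adds a criterion. The covariate gave 6092 genes for ERF115-SRDX against WT, 8221 for ERF115OX against ERF115-SRDX and 1022 opposite calls; ERF115-SRDX 2 alone gave 1285 opposite calls, from fewer samples. A fit of only ERF115OX and ERF114OX called 917 genes, from fewer libraries to estimate the spread. With an estimated correlation camera called 0 lists in each of the 5 comparisons. Fry, which does not compare a list with other genes, called 33 for ERF115-SRDX against WT, 8 between the overexpressors and 34 between ERF115OX and ERF115-SRDX.

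With 1 library of the groups compared left out, totals ran from 5482 to 7318 for ERF115OX against WT, 6485 to 8115 for ERF114OX, 10377 to 11068 for ERF115-SRDX, 600 (without ERF115OX 2) to 2204 (without ERF115OX 1) between the overexpressors, with 887, 841 and 922 without ERF115OX 3, ERF114OX 2 and ERF114OX 3, and 11630 to 12400 between ERF115OX and ERF115-SRDX. Shared calls ran from 3792 to 5256 and opposite calls from 1491 to 1950. A library of another group left out gave at most 7796, 9006, 11970 and 13228 genes for ERF115OX, ERF114OX and ERF115-SRDX against WT and ERF115OX against ERF115-SRDX, 5519 shared and 2111 opposite calls. ERF115 ran from 8.29 to 11.58 in ERF115OX and from 9.51 to 12.80 in ERF115-SRDX, and ERF114 from 11.02 to 11.83 in ERF114OX. With the replicate number as a block the totals were 7192, 8400, 11562, 1490 and 12947, with 5125 shared and 1904 opposite calls. The numbers do not pair the libraries: over 18 pairs with the same number the correlation of deviations across genes ran from -0.283 to 0.440, and 4 of 12 libraries had their closest partner under their own number.

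The values that turned sign were all of uncalled results, and the cause was not tested. With 1 library of the groups compared left out, ERF115OX against WT ranged from -0.105 to 2.458 for ERF114, -0.296 to 0.056 for ERF108, -0.085 to 0.035 for ERF109, -0.53 to 0.055 for ERF111 and -0.046 to 0.031 for ERF112. ERF112 ranged from -0.01 to 0.183 in ERF114OX against WT, and ERF114 from -0.159 to 0.65 in ERF115-SRDX against WT. Between the overexpressors the ranges were -0.022 to 0.33 for ERF108, -0.027 to 0.558 for ERF111, -0.189 to 0.004 for ERF112, -0.026 to 0.11 for PSK1 and -0.103 to 0.123 for PSK3. ERF114 ranged from -0.258 to 2.306 between ERF115OX and ERF115-SRDX. Quantile normalization gave 0.089 for ERF109 and 0.018 for ERF112 in ERF115OX and 0.007 for PSKR2 in ERF115-SRDX. The covariate gave 0.002 for ERF109 in ERF115OX, and -1.119 for ERF114 and 0.005 for PSKR2 in ERF115-SRDX. Without ERF114OX 1 and ERF115-SRDX 2, ERF112 was at -0.01 in ERF114OX against WT and 0.004 between the overexpressors. Without ERF115-SRDX 1 and 3, ERF114 was at -0.416 in ERF115-SRDX against WT. Genes with fewer than 3 reads per library lie under the floor at this depth.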

Other observations

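All genes in this part were chosen after their values were seen and are given as values. MRD1, AT1G07887 and HEI10 were taken from the genes named above, and the others from lists fixed before. Among wound and regeneration regulators, WIND1, an AP2/ERF gene of wound-induced dedifferentiation, stood at 7323 ± 367 normalized counts in WT, 11406 ± 245 in ERF115OX, 11854 ± 206 in ERF114OX and 3028 ± 56.4 in ERF115-SRDX. WIND2 stood at 1529 ± 58.7, 2224 ± 18.8, 2220.1 ± 31.9 and 975.4 ± 24.0 in the same order. The cytokinin synthesis gene IPT3 stood at 419 ± 20.3, 789 ± 22.02, 658 ± 60.7 and 222 ± 26.2. The cytokinin oxidase gene CKX4 stood at 556 ± 32.9, 636 ± 21.0, 702 ± 47.2 and 33.8 ± 3.94. In ERF115-SRDX limma called 3 of 13 wound regulators higher and 5 lower, and camera did not call that list (adjusted p = 0.56). Of 21 cytokinin genes 6 were higher and 4 lower in ERF114OX, and 4 and 10 in ERF115-SRDX. Camera called that list in neither line (adjusted p = 0.57 and 0.11).

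In the iron uptake list, which camera called in none of the 3 lines (adjusted p = 0.28, 0.99 and 0.54 against WT; limma called 6 higher and 3 lower, 5 and 7, and 6 and 3 of 16), the iron transporter gene IRT1 stood at 2686 ± 305 in WT, 6397 ± 1362 in ERF115OX, 6983 ± 1164 in ERF114OX and 3386 ± 499 in ERF115-SRDX. CYP82C4, a P450 of the iron deficiency response, stood at 383 ± 103, 1376 ± 286, 1943 ± 245 and 912 ± 214. In the flavonoid list, also not called against WT (camera adjusted p = 0.75, 0.32 and 0.37; limma called 6 higher and 4 lower, 6 and 4, and 1 and 5 of 11), the first enzyme, CHS, stood at 15904 ± 943, 24238 ± 2333, 25421 ± 492 and 15278 ± 2099, whereas the anthocyanin glycosylation gene UF3GT stood at 88.0 ± 61.5, 6.80 ± 1.27, 12.9 ± 4.11 and 7.57 ± 7.98.

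The neighbours MRD1, AT1G07887 and HEI10 had low counts in both lines that carry an ERF115 construct and not in ERF114OX. As the labels do not say how many independent lines were used, these low counts cannot be tied to the construct. HEI10 stood at 2216 ± 89.9 in WT, 145 ± 5.47 in ERF115OX, 2830.3 ± 171 in ERF114OX and 208 ± 30.3 in ERF115-SRDX.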
